A study of Homo sapiens with 2 samples.

How the data were processed

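RNA was measured in 2 libraries, 1 from wild-type H1 cells and 1 from MEIS1-/- H1 cells, both at day 6 of megakaryocytic culture. Per the labels' protocols, cells were differentiated for 12 days on mAGM-S3 stroma and replated on inactivated mAGM-S3 for 6 days with a ROCK inhibitor (10 µM), thrombopoietin (50 ng/mL), stem cell factor (20 ng/mL) and interleukins 3, 6, 9 and 11 (at 20, 10, 20 and 20 ng/mL). RNA was extracted with Trizol, and 2 µg of total RNA went into an Illumina TruSeq RNA kit, per the labels' protocols. The sources used here do not state a sort, so each library may hold every cell type of the culture, and the stroma was mouse.

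The authors deposited 1 table per library with expected counts, FPKM and transcript length for each gene, under the column names that RSEM writes, per the file headers. BWA, Bowtie and RSEM with genome build hg19 were named without versions, roles or order, per the submitters' processing notes. The series' design text instead names BWA with ANOVA, and TopHat with Cufflinks, which do not write tables with these columns. The tables were therefore read as RSEM output. The deposited expected counts are estimated reads per gene that need not be whole, since RSEM divides reads shared by several transcripts, and 65.5% (wild type) and 65.7% (MEIS1-/-) of them lay within 0.005 of a whole number. The deposited FPKM values are scaled by the authors for transcript length and library total, and the smallest listed value was 0.01 in both tables, so a gene that is not listed was taken as 0. Strand use in counting is not given in the sources used here, so overlapping antisense genes cannot be separated.

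Of 19575 genes listed in either library, 17203 were listed in both, 1585 in the wild-type table alone and 787 in the MEIS1-/- table alone. Genes are Entrez identifiers in the files. Symbols came from a RefSeq gene table of GRCh38, used for names alone, and 19496 identifiers matched. The 79 others took 0.175% of the wild-type counts and 0.123% of the MEIS1-/- counts. No coordinates are given because the reference and the files use different builds. Transcript GC content came from GENCODE transcript sequences matched by RefSeq accession and was available for 12532 of the 12939 genes past the filter (96.9%), and for at least 88.9% of each list.

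Expected counts were rounded to whole numbers. Library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.10 for wild type and 0.909 for MEIS1-/-. The log2 ratio of MEIS1-/- over wild type was taken on scaled counts after adding 0.5, for genes with at least 20 counts in at least 1 library. A gene was called higher or lower at 2-fold or more. No p-value across genes is given, since there is 1 library per genotype. Exact 95% Clopper-Pearson intervals of the ratio came from the binomial share of each gene's counts. They leave out culture, library and amplification differences and the division of shared reads by RSEM. A fold against 0 counts was computed against a floor of 3 counts in that library and is a lower bound. Totals of 4793898 and 4843476 counts are shallow, and a gene at 20 counts has a wide interval.

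Before the data were examined, 36 gene lists were fixed from the lineage, the other cell types that the culture could hold and common stress and growth programmes. Of their 1000 entries, 15 matched no gene. Each list with at least 5 genes past the filter was described by its median log2 ratio and by that median's percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A median outside the central 95% is described as standing apart. Some lists share genes and are not independent. The genes named were also set by a rule fixed beforehand. It took MEIS1, the 10 highest and 10 lowest ratios among genes with at least 200 counts in the higher library, up to 4 genes of each list in the direction of its median and up to 2 in the other, all the megakaryocyte-erythroid transcription factors, and a fixed set of lineage genes. Genes outside that rule are named as chosen after their values were seen.

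The ratio, interval and list steps were tested on simulated data for this comparison. Counts for 19575 genes were drawn from the real means and library sizes, with 200 genes changed 4-fold. Of these, 99.5% were recovered at 2-fold or more with a median log2 change of 1.98, and 95.7% of the intervals held the true value. Among unchanged genes, 0.536% passed 2-fold. Of 100 lists without change, 7 lay outside the central 95%, and a list planted 2-fold lower lay at percentile 0. The simulated counts held counting error alone, with no difference between cultures, and the simulated lists were random genes. These rates check the steps and are not error rates for the real libraries.

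Alternatives fixed beforehand were scaling by library totals, median-of-ratios scaling in DESeq2 1.42.0, the deposited FPKM plus 1, no filter on low counts, a filter at 100 counts, a pseudocount of 5, calls at the bound of the interval nearest to no difference, lists without genes held by several lists, and list means. Corrections for transcript length, GC content and both, by the median ratio in 20 bins, and library totals without globin genes were added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Mouse reads were not separated, and reads were not realigned.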

Results

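The series held 2 RNA-seq libraries of cells derived from H1, a human embryonic stem cell line. One library came from wild-type cells and the other from cells in which MEIS1 had been deleted on both alleles (MEIS1-/-). MEIS1 encodes a homeodomain transcription factor of the TALE class. Cells had first been differentiated towards blood for 12 days on mAGM-S3, a mouse stromal line, and were then kept for another 6 days on the same kind of stroma in medium with thrombopoietin, stem cell factor and interleukins that favour megakaryocytes, the precursors of platelets. The wild-type library held 4793898 estimated counts over 18788 listed genes, and the MEIS1-/- library held 4843476 over 17990. With 1 library per genotype there was no replicate check, so no test between the genotypes was possible and differences are described by size. The bracketed ranges are exact 95% Clopper-Pearson intervals, and they cover counting error between these 2 libraries only.

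The design asks how the transcriptome of day 6 megakaryocytic cultures differed without MEIS1. MEIS1 itself (Entrez4211) had 1359 counts in the wild-type library and 83 in the MEIS1-/- library. On the TMM-scaled library size these were 257.6 and 18.9 CPM, which was 13.6-fold lower in the MEIS1-/- library (log2 ratio -3.76, interval -4.11 to -3.45). The labels do not say which part of the gene was deleted, so the remaining counts do not go against the genotype given for that library. The platelet gene SELP, which was not the targeted gene, was also 13.6-fold lower. The size of the MEIS1 drop therefore does not by itself check the deletion. Megakaryocyte and platelet genes were lower in the MEIS1-/- library, with a median 6.60-fold difference over 24 surface receptor genes. Erythroid genes were higher, by a median of 4.61-fold over 34 genes. Interferon-response genes were lower by a median of 5.86-fold over 28 genes.

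Across the 12939 genes with at least 20 counts in at least 1 library, the median log2 ratio of MEIS1-/- over wild type was 0.02, with quartiles of -0.46 and 0.41. Of these genes, 798 were at least 2-fold higher in the MEIS1-/- library, 1481 were at least 2-fold lower and 10660 (82.4%) lay within 2-fold. At 8-fold or more, 43 genes were higher and 153 were lower. The split depended on the scaling. Scaling by library totals gave 487 higher and 2142 lower, so that 18.5% of the genes past 2-fold were higher against 35% in the main scaling, and moved the median of all genes by -0.28 on the log2 scale. The deposited FPKM plus 1 gave 346 higher and 1435 lower, 19.4% higher, and the median of all genes was then -0.22. Globin genes took 3.44% of the counts in the wild-type library and 15.7% in the MEIS1-/- library.

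**Figure D1:**
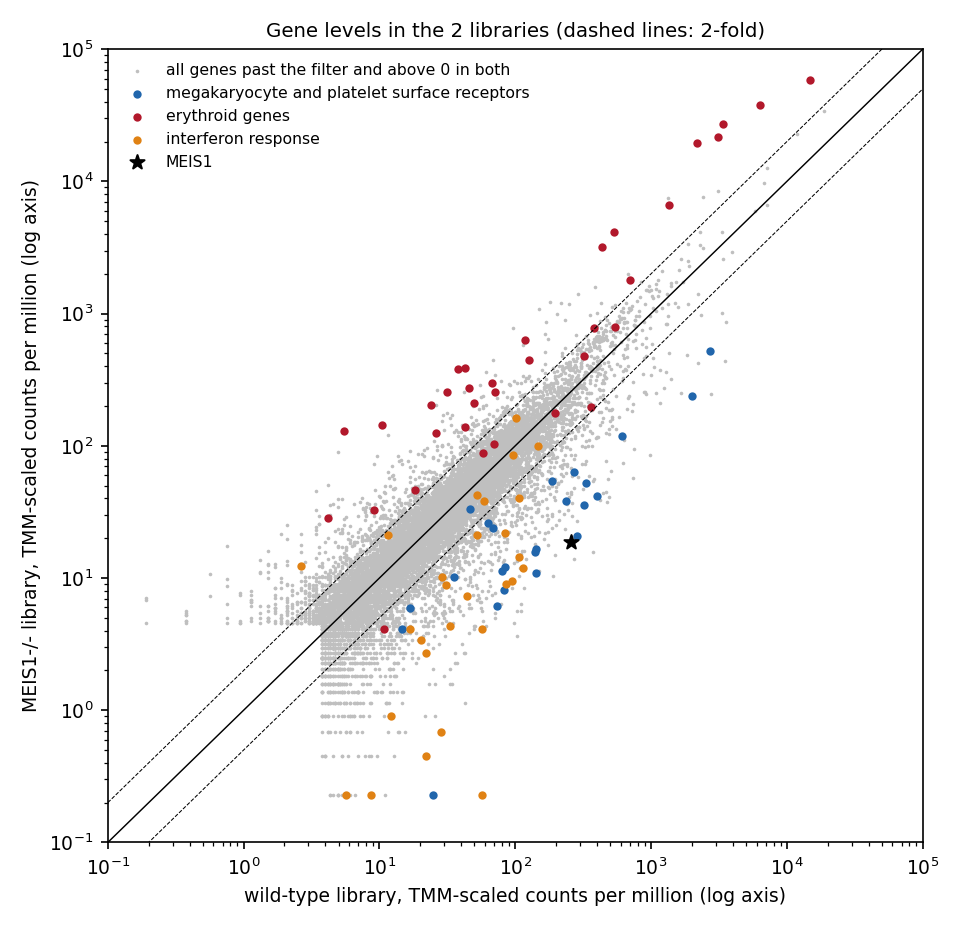
Each point is 1 gene, with its scaled CPM in the wild-type library on the horizontal axis and in the MEIS1-/- library on the vertical axis, both on log scales, and genes at 0 in a library are not drawn. Coloured points mark the gene lists named in the legend, with megakaryocyte surface receptors below the diagonal (23 of 24 at least 2-fold lower) and most erythroid genes above it (27 of 34 at least 2-fold higher).

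Among genes with at least 200 counts in the higher library, the 10 lowest in the MEIS1-/- library were led by NUDT4P2 and IFI27. NUDT4P2 had 756 counts in the wild-type library and was at 0 in the MEIS1-/- library, at least 210-fold lower against a floor of 3 counts. It is a near-identical copy of NUDT4 and NUDT4B, both looked up after the values were seen and higher in the MEIS1-/- library, so its value is uncertain. IFI27, an interferon-induced gene, had 303 counts against 1 (log2 ratio -7.44, -13.29 to -5.49). The others were PTCRA, TFPI2, ABCC3, PITPNM2, COL24A1, PDE3A, EHD3 and MAST4, between 34.5-fold and 18.0-fold lower. PDE3A, the platelet cAMP phosphodiesterase, had 580 counts against 25 (log2 ratio -4.25, -4.91 to -3.70). The 10 highest were AHSP, SYP, GYPB, STRA6, LTF, SLC30A10, GYPA, SELENBP1, HBM and HBZ. AHSP, the chaperone of alpha-globin, had 29 counts in the wild-type library and 566 in the MEIS1-/- library, 23.0-fold higher (log2 ratio 4.52, 4.01 to 5.14). HBZ, the embryonic zeta-globin gene, was 8.99-fold higher with 86347 counts against 11508.

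Surface receptors of megakaryocytes and platelets were lower together. Of 24 genes, 23 were at least 2-fold lower and none was higher. The median log2 ratio was -2.72, below all 10000 random lists matched on size and expression, whose central 95% ran from -0.26 to 0.32. The exception was CD36, named after its value was seen, at 1.38-fold lower. P2RY12, the platelet ADP receptor, had 131 counts against 1 (log2 ratio -6.24, -12.09 to -4.27). SELP and GP5 were 13.6-fold and 11.8-fold lower, and CD226 had 754 counts against 48. GP9 and GP1BA, subunits of the receptor for von Willebrand factor, were 9.61-fold and 9.02-fold lower. ITGB3 and ITGA2B, which encode the fibrinogen receptor subunits, were 8.38-fold (log2 ratio -3.07, -3.16 to -2.98) and 5.24-fold lower (log2 ratio -2.39, -2.45 to -2.33). MPL, the thrombopoietin receptor, was 3.46-fold lower with 188 counts against 45.

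Platelet granule cargo and biogenesis genes were also lower. Of 26 genes, 17 were at least 2-fold lower and none was higher, with a median log2 ratio of -1.87 that lay below all random lists. The chemokine genes PPBP and PF4 were 11.2-fold lower (14514 counts against 1082, log2 ratio -3.48, -3.58 to -3.40) and 6.57-fold lower (8733 against 1109). VWF, SPARC and PDGFA were 11.3-fold, 11.9-fold and 15.5-fold lower. PF4V1, a near-identical copy of PF4 and so uncertain, had 60 counts against 0, at least 16.7-fold lower against the floor of 3 counts. With that gene at its bound the list's median was still -1.87. HPS3 and VPS33B, which act in granule formation, were 1.53-fold and 1.41-fold higher.

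In the list of cytoskeleton and proplatelet formation genes, 22 of 30 were at least 2-fold lower and none was higher (median log2 ratio -1.52, below all random lists). TUBB1, the platelet beta-tubulin, had 11620 counts against 1870 and was 5.18-fold lower (log2 ratio -2.37, -2.45 to -2.30). MYLK, TUBA8 and VCL were 10.1-fold, 5.61-fold and 5.51-fold lower. RHOB lay at a log2 ratio of 0.41, and CNN2 at 0.04 with a negative value under library total scaling and with FPKM plus 1. Of 25 platelet signalling genes, 13 were at least 2-fold lower and none was higher (median log2 ratio -1.10, below all random lists). ADCY6, RGS18 and ARHGAP6 were 7.67-fold, 6.53-fold and 6.38-fold lower. VAMP8 lay at 0.49 and PTPN6 at 0.24, the latter negative under library total scaling and with FPKM plus 1.

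**Figure D2:**
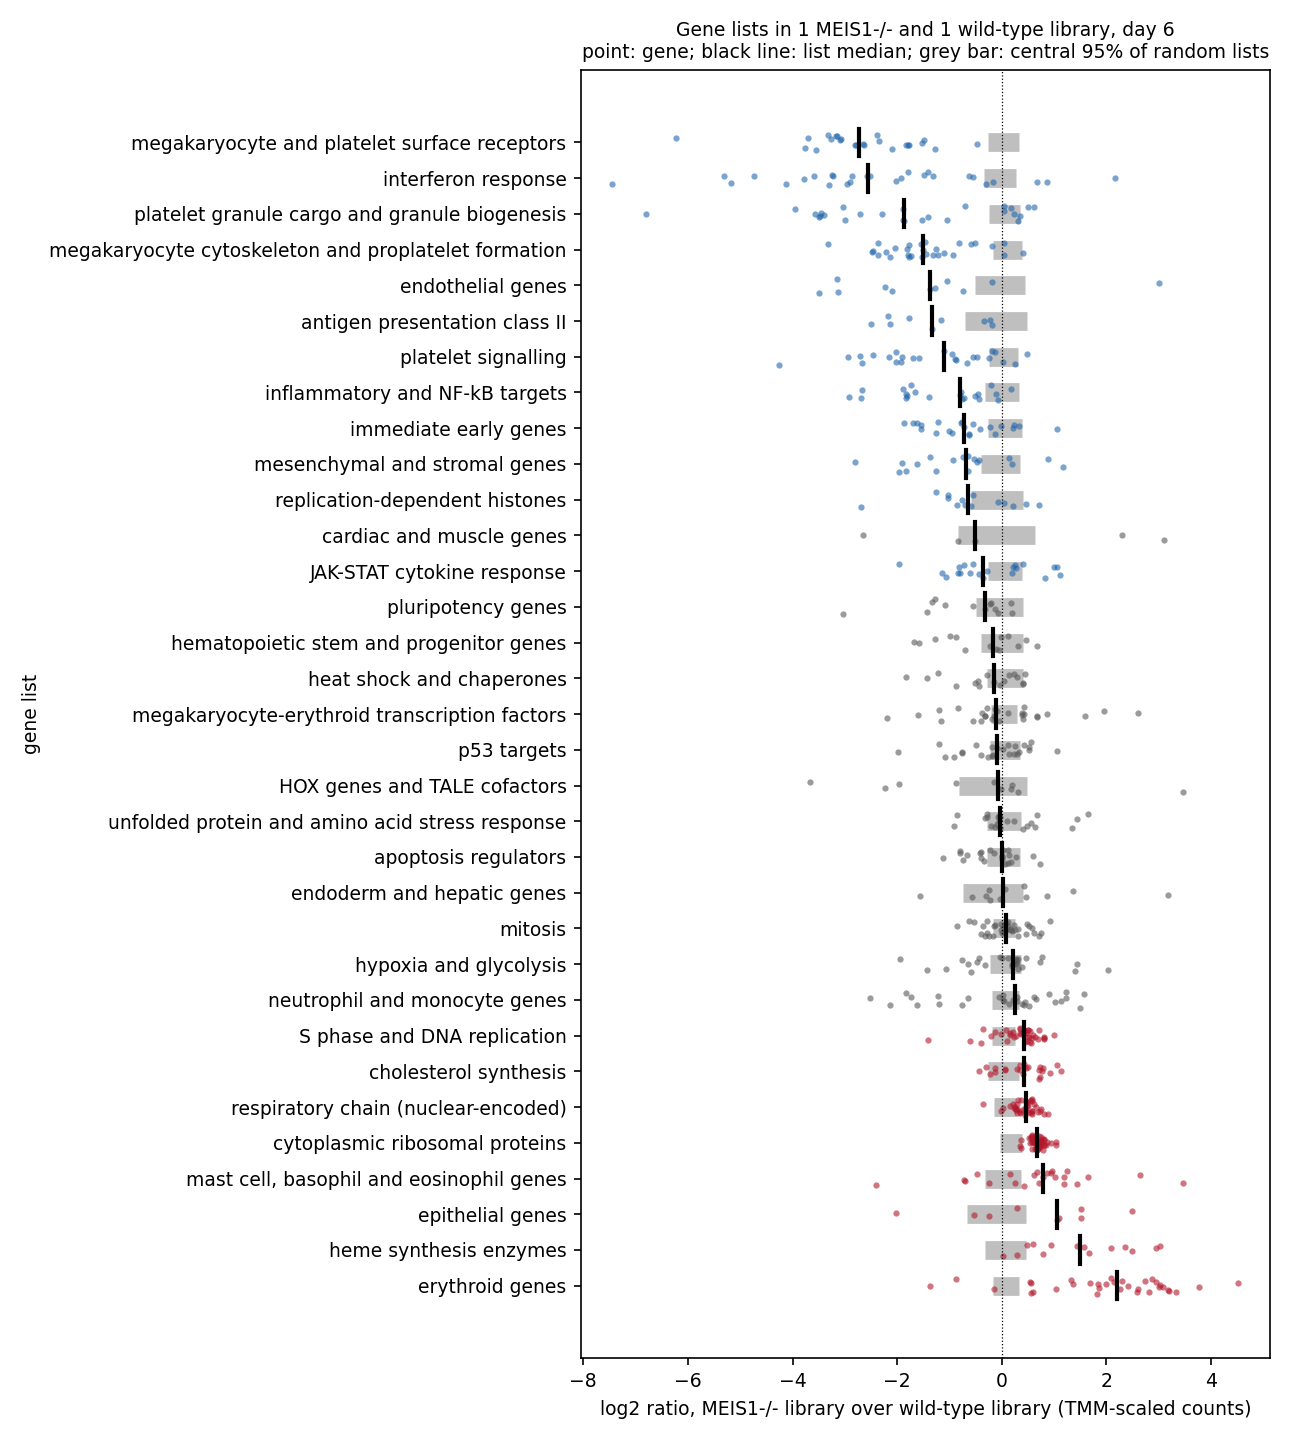
Each row is 1 fixed gene list, with the log2 ratio of MEIS1-/- over wild type on the horizontal axis. Points are genes past the filter (PF4V1, at 0 in the MEIS1-/- library, is drawn at its value with the pseudocount), coloured blue or red where the list's median (black line) lies below or above the central 95% of 10000 random lists (grey bar), with surface receptors at -2.72, interferon response at -2.55 and erythroid genes at 2.21.

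The transcription factors of the megakaryocyte and erythroid lineages did not stand apart as a list. Of 28 genes, 3 were at least 2-fold higher, 4 were lower and 21 lay within 2-fold. The median log2 ratio was -0.12, at percentile 9.95 of the random lists, and the mean was 0.02, of the opposite sign. The 4 lower genes were MEF2C, FLI1, ETV6 and HHEX, at 4.60-fold, 3.03-fold, 2.29-fold and 2.24-fold. FLI1, an ETS factor of the megakaryocyte programme, had 767 counts against 211 (log2 ratio -1.60, -1.83 to -1.38). The 3 higher genes were KLF1 at 6.07-fold, LMO2 at 3.89-fold and TCF3, with 259 counts against 650 (log2 ratio 1.59, 1.38 to 1.80). KLF1, the erythroid Kruppel-like factor, had 239 counts against 1213 (log2 ratio 2.60, 2.40 to 2.81). GATA1 was 1.59-fold higher (log2 ratio 0.67, 0.54 to 0.79) and TAL1 1.47-fold lower (log2 ratio -0.56, -0.63 to -0.49). RUNX1 had a log2 ratio of -0.18 (-0.33 to -0.03) and NFE2 one of 0.41. MYB lay at 0.11 (-0.07 to 0.29) and turned negative under library total scaling and with FPKM plus 1.

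**Figure D3:**
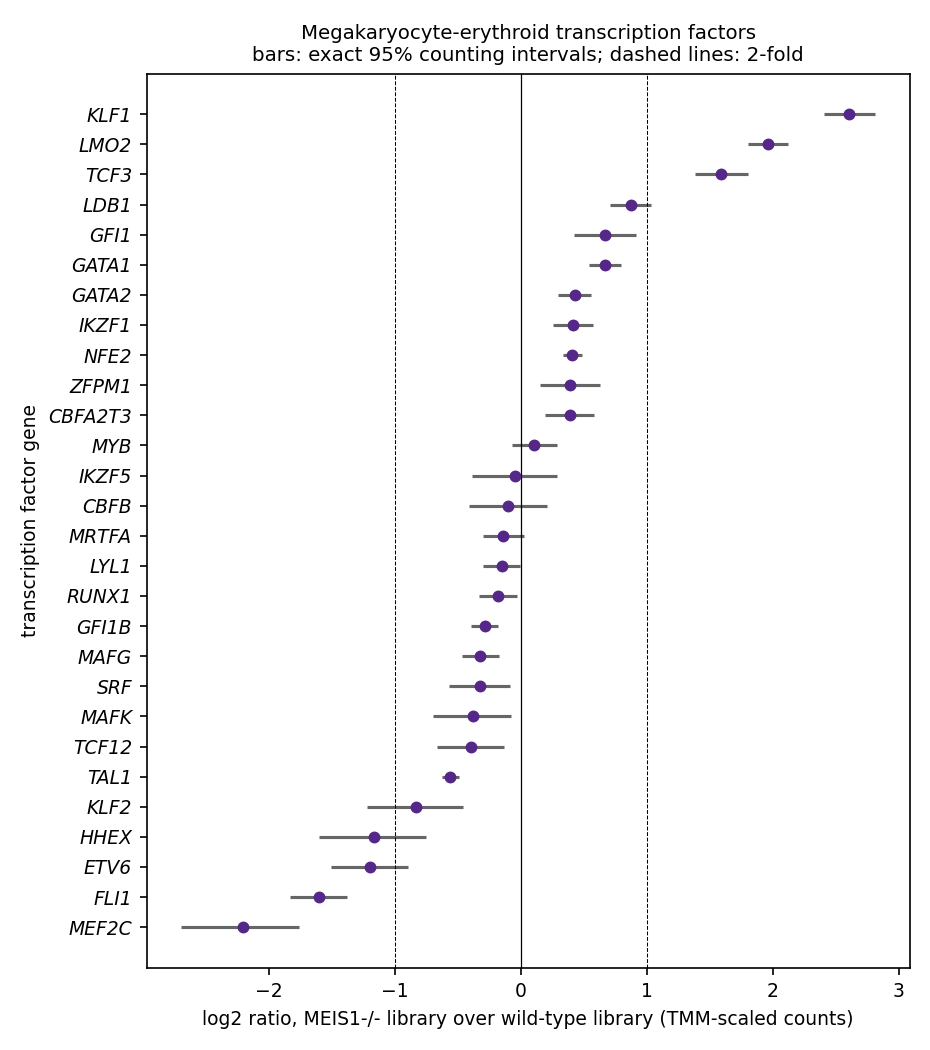
Log2 ratio of MEIS1-/- over wild type (horizontal axis) for the megakaryocyte-erythroid transcription factors past the filter, 1 row per gene, with bars for the 95% counting interval. KLF1 (2.60), LMO2 (1.96) and TCF3 (1.59) lie highest, and MEF2C (-2.20), FLI1 (-1.60), ETV6 (-1.19) and HHEX (-1.16) lie lowest.

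Erythroid genes were higher in the MEIS1-/- library. Of 34 genes, 27 were at least 2-fold higher and 1 was lower, with a median log2 ratio of 2.21 that lay above all random lists (central 95% from -0.17 to 0.33). The embryonic globin gene HBE1 was 5.97-fold higher, with 33575 counts against 167238. HBG2 and HBG1, the fetal gamma-globin genes, were 3.97-fold and 4.93-fold higher, and their near-identical sequences make the division of reads between them uncertain. The glycophorin genes GYPB and GYPA were 13.7-fold and 10.1-fold higher, and they too are close copies. HBD, the delta-globin gene, was the 1 lower gene, with 57 counts against 18 (log2 ratio -1.38, -2.25 to -0.62). TRIM58 was 1.84-fold lower. The adult beta-globin gene HBB, looked up after the values were seen, stayed below the filter at 8 and 18 counts.

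Genes of the heme synthesis list were higher as well. The list also holds transporter genes and HMOX1, named after its value was seen, which encodes a heme-degrading enzyme. Of 14 genes, 8 were at least 2-fold higher and none was lower (median 2.84-fold, above all random lists). HMBS, ALAS2, SLC25A37 and FECH were 8.11-fold, 7.68-fold, 5.64-fold and 5.13-fold higher. ALAS2 encodes the first enzyme of the pathway in red cells and FECH the last.

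Markers of other blood cells went both ways. Of 30 neutrophil and monocyte genes, 6 were at least 2-fold higher and 7 were lower. Their median log2 ratio was 0.24, at percentile 89.6, and the mean was -0.04, of the opposite sign. S100A9, S100A8, S100A12 and ELANE were 2.97-fold, 2.82-fold, 2.35-fold and 2.35-fold higher, whereas VCAN and FCGR3A were 5.73-fold and 4.40-fold lower. The deposited FPKM of S100A12 (30.0 and 58.0) and ELANE (69.1 and 133) were within 2-fold. Those of S100A9, S100A8, VCAN and FCGR3A stayed past it, so the split of the list depended on the scaling. SPI1, the myeloid ETS factor, had 759 counts against 773 (log2 ratio 0.29, 0.14 to 0.43). Of 23 mast cell, basophil and eosinophil genes, 8 were at least 2-fold higher and 1 was lower (median log2 ratio 0.78, above all random lists). Of the higher genes, CPA3, HDC, RNASE2 and RNASE3, named after their values were seen, were within 2-fold by deposited FPKM. These were 56.5 and 105.7, 91.9 and 172.7, 516.8 and 854.5, and 47.5 and 92.7. CLC, PRG3, CCR3 and FCER1A stayed past 2-fold, so the count of higher genes depended on the scaling. CLC and PRG3, genes expressed in eosinophils, were 3.15-fold and 2.71-fold higher, with 33587 and 37242 counts in the MEIS1-/- library. CCR3 had 2 counts against 23 and FCER1A 8 against 44. MITF was 5.30-fold lower, and TPSAB1, a tryptase gene with near-identical copies, lay at -0.73. The eosinophil genes PRG2, EPX, PRG3 and CLC together took 3.97% of the wild-type counts and 6.62% of the MEIS1-/- counts, a sum formed after the values were seen. IL5RA and SIGLEC8 of the same list, also picked after their values were seen, lay at log2 ratios of 0.25 and 0.15. Only 4 lymphoid genes passed the filter, 1 at least 2-fold higher and 1 lower, too few for a comparison with random lists.

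The endothelial genes past the filter were lower. Of 27 listed, 11 passed, of which 8 were at least 2-fold lower and 1 was higher (median log2 ratio -1.37, percentile 0.01). CDH5 and PLVAP, looked up after the values were seen, were nearly absent from both libraries. CDH5 had 2 counts against 0 and PLVAP 0 against 1. VWF and ESAM also belong to the megakaryocyte lists. ESAM, KDR and LYVE1 were 8.85-fold, 8.80-fold and 4.72-fold lower, and APLNR, a receptor of early mesoderm and endothelium, was the higher one, with 19 counts against 130. Of 14 hematopoietic stem and progenitor genes, none was at least 2-fold higher and 3 were lower (median log2 ratio -0.17, percentile 15.3). Without the filter on low counts the median was -0.79 and stood apart (percentile 0.21). MYCN and LIN28B were 3.19-fold and 2.42-fold lower and NRIP1 had 407 counts against 113. KIT, the stem cell factor receptor, was 1.63-fold lower, PTPRC lay at -0.06 (-0.24 to 0.12), and GFI1 and CD44 lay at 0.67 and 0.47. CD34 stayed below the filter at 11 and 2 counts.

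Of 13 pluripotency genes, none was at least 2-fold higher and 5 were lower (median log2 ratio -0.32, percentile 11.4). Their mean was -0.72, outside the random range (percentile 2.13). LEFTY1, DNMT3B and LIN28A were 8.21-fold, 2.69-fold and 2.53-fold lower, and SALL4 and PODXL lay at 0.20 and 0.17, with negative values under library total scaling and with FPKM plus 1. Mesenchymal and stromal genes were lower, with 7 of 18 at least 2-fold lower and 1 higher (median log2 ratio -0.69, percentile 0.15). COL6A3, PDGFRA, FN1 and LUM were 6.96-fold, 3.91-fold, 3.76-fold and 3.58-fold lower, while TAGLN was 2.24-fold higher and S100A6 1.84-fold higher. The deposited FPKM of TAGLN (15.06 and 27.45) were within 2-fold. The stroma was mouse, and the files do not show how many of these reads came from mouse RNA.

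Other tissue markers were sparse. Of 12 endoderm and hepatic genes, 2 were at least 2-fold higher and 1 was lower (median log2 ratio 0.01, percentile 71.4). TF, the transferrin gene, had 11 counts against 87, HNF4A had 9 against 20 and TTR had 26 against 7. The deposited FPKM of HNF4A were 0.86 and 0.90, within 2-fold. Of 9 epithelial genes, 5 were at least 2-fold higher and 1 was lower (median log2 ratio 1.05, above all random lists). KRT19, EPCAM and ELF3 were 5.59-fold, 2.87-fold and 2.86-fold higher, and LCN2 was 4.04-fold lower. Without the filter on low counts the epithelial median was -0.04, inside the random range. Of 5 cardiac and muscle genes, 2 were at least 2-fold higher and 1 was lower, with a median of -0.52 (percentile 9.20) and a mean of 0.28, of the opposite sign. DES and MYL4 were 8.55-fold and 4.92-fold higher and RYR2 was 6.27-fold lower. Only 4 neural genes passed the filter, of which 2 were at least 2-fold higher. One of them was SYP, with 26 counts against 394.

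The HOX genes and TALE cofactors did not stand apart. Of 10 genes, 1 was at least 2-fold higher and 3 were lower (median log2 ratio -0.08, percentile 57.6). PBX1, whose product pairs with MEIS proteins on DNA, was 3.91-fold lower with 779 counts against 166 (log2 ratio -1.97, -2.22 to -1.73). PBX4 and MEIS3 had 37 counts against 2 and 30 against 5. HOXB9 had 3 counts against 32 (log2 ratio 3.46, 2.00 to 6.03).

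Interferon-response genes were lower in the MEIS1-/- library. Of 28 genes, 21 were at least 2-fold lower and 1 was higher, with a median log2 ratio of -2.55 that lay below all random lists. OAS1 and OAS2, sensors of double-stranded RNA, had 116 counts against 2 (log2 ratio -5.31, -8.66 to -3.71) and 149 against 3 (log2 ratio -5.17, -7.67 to -3.80). USP18 had 46 counts against 1. ISG20 was the 1 higher gene, with 14 counts against 54, and IFI35 lay at 0.86. Beside this list, the monocyte and macrophage genes VCAN and FCGR3A were 5.73-fold and 4.40-fold lower, while the list of neutrophil and monocyte genes that holds them had a median of 0.24, or of -0.15 and below the random range after a correction for transcript length and GC content. Genes of class II antigen presentation were lower too, with 6 of 9 at least 2-fold lower and none higher (median log2 ratio -1.33, percentile 0.06). HLA-DRA had 131 counts against 19, 5.64-fold lower, and HLA-DPA1, HLA-DMB and HLA-DRB1 were 4.49-fold, 4.41-fold and 3.42-fold lower.

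Inflammatory and NF-kB target genes were lower. Of 21 genes, 10 were at least 2-fold lower and none was higher (median log2 ratio -0.80, below all random lists). The chemokine genes CXCL3, CXCL2 and CXCL8 were 7.53-fold, 6.36-fold and 3.72-fold lower, and TNF had 34 counts against 4. Beside this list and the class II genes, the monocyte and macrophage genes IRF8, CD14, CD163, CSF1R and CD68, picked after their values were seen, were between 3.56-fold and 2.29-fold lower, while LYZ and MNDA of the same list, picked likewise, lay at 0.61 and 0.38. Of 23 immediate early genes, 8 were at least 2-fold lower and 1 was higher (median log2 ratio -0.71, percentile 0.01). FOS, DUSP1, FOSB and NR4A2 were 3.68-fold, 3.26-fold, 3.08-fold and 2.90-fold lower. MYC was the higher one at 2.07-fold, but its deposited FPKM of 29.8 and 50.6 were within 2-fold, and JUND lay at 0.33. JAK-STAT cytokine response genes had 3 of 21 at least 2-fold lower and 2 higher (median log2 ratio -0.37, percentile 0.72). DUSP5, ID1 and JAK2 were 3.92-fold, 2.21-fold and 2.09-fold lower, and STAT5B was 2.15-fold higher. This list no longer stood apart with a filter at 100 counts or by its mean.

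Of 17 heat shock and chaperone genes, none was at least 2-fold higher and 3 were lower (median log2 ratio -0.15, percentile 9.41). HSPA1B and HSPA1A, a near-identical pair and so uncertain one by one, were 3.56-fold and 2.32-fold lower, and HSPB1 was 2.68-fold lower. In the unfolded protein and amino acid stress response, 3 of 23 genes were at least 2-fold higher and none was lower. The median was -0.04 (percentile 24.8) and the mean 0.18, of the opposite sign. ASNS and DDIT4 were 3.14-fold and 2.69-fold higher and PSAT1 was 1.90-fold lower. The deposited FPKM of PSAT1 (13.39 and 5.95) and PHGDH (10.63 and 4.77) differed by more than 2-fold, so this list's count of lower genes depended on the scaling. Of 25 p53 target genes, 1 was at least 2-fold higher and 3 were lower (median log2 ratio -0.10, percentile 13.1). CDKN1A, the cell cycle inhibitor p21, was 3.95-fold lower with 2580 counts against 544, and TP53I3 was 2.07-fold higher. The deposited FPKM of TP53I3 (7.31 and 11.1) were within 2-fold. Of 23 apoptosis regulators, none was at least 2-fold higher and 1, APAF1, was lower at 2.18-fold (list median 0.00, percentile 36.8, and mean -0.17). After a correction for transcript length the list's median was -0.27, below the random range (percentile 1.23). BCL2L1, a survival factor of megakaryocytes and erythroid cells, was 1.75-fold lower. Its deposited FPKM of 421.5 and 201.7 differed by more than 2-fold, so the count of lower genes depended on the scaling.

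Genes of S phase and DNA replication were slightly higher as a list. None of 41 was at least 2-fold higher and 1 was lower, and the median log2 ratio of 0.42 lay above all random lists. TK1 and DHFR lay at 1.00 and 0.80, and E2F1 was the lower one at 2.66-fold. None of 38 mitosis genes passed 2-fold in either direction (median log2 ratio 0.07, percentile 59.1). AURKB and AURKA lay at 0.91 and 0.75 and ASPM at -0.87. Of 14 replication-dependent histone genes, none was at least 2-fold higher and 4 were lower (median log2 ratio -0.64, percentile 1.61). H4C8 had 34 counts against 4, and H2BC12 and H1-2, the deeper genes with 972 and 1228 counts in the wild-type library, lay at 0.71 and 0.47. With a filter at 100 counts, or by its mean, this list no longer stood apart. Histone genes are close copies of one another and their values are uncertain.

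All 54 cytoplasmic ribosomal protein genes had log2 ratios above 0, with 2 at least 2-fold higher. The median was 0.67, 1.59-fold, above all random lists. RPLP1 and RPS12 were 2.05-fold and 2.04-fold higher, but their deposited FPKM (1919 and 3222, and 998 and 1670) were within 2-fold. Ribosomal protein genes have many processed copies in the genome, which makes single values uncertain. Of 40 nuclear-encoded respiratory chain genes, none passed 2-fold in either direction, and the median log2 ratio of 0.46 lay above all random lists. COX7C and CYC1 lay at 0.88 and 0.81 and NDUFA6 at -0.35. Beside both lists, short transcripts had higher ratios than long ones. From the fifth of genes with the shortest transcripts to the fifth with the longest, the median log2 ratio went from 0.32 to -0.30. After a correction for this trend the respiratory chain median was 0.10, inside the random range. The ribosomal protein median was then 0.29 (percentile 98.2), still above its range.

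Of 23 cholesterol synthesis genes, 2 were at least 2-fold higher and none was lower (median log2 ratio 0.43, percentile 99.6). MVD and LSS were 2.20-fold and 2.07-fold higher and INSIG1 lay at -0.44. The deposited FPKM of MVD (20.3 and 36.7) and LSS (16.1 and 27.2) were within 2-fold. Of 28 hypoxia and glycolysis genes, 3 were at least 2-fold higher and 3 were lower (median log2 ratio 0.21, percentile 80.0). The glucose transporter genes went opposite ways. SLC2A1 was 4.06-fold higher with 2052 counts against 6947 (log2 ratio 2.02, 1.95 to 2.09), and SLC2A3 was 2.68-fold lower with 7101 against 2208 (log2 ratio -1.42, -1.49 to -1.36). EGLN3 was 3.83-fold lower. No mitochondrially encoded gene was listed in either library. In all, 20 of the 33 lists with enough genes lay outside the central 95% of their random lists, 8 above and 12 below. Chance alone would put about 1.6 of 33 independent lists there if the genes of a list varied independently. Genes of the same list can vary together between any 2 cultures, whatever their genotype. The number of lists outside the range is therefore a description and not a test of the genotype.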

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

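The length, GC content and globin alternatives were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out and no other split of the samples exists. Over all alternatives the surface receptor median stayed between -2.997 and -2.65, the erythroid median between 1.795 and 2.26 and the interferon-response median between -2.82 and -2.03. Among list medians, 378 of the recomputed values kept their side of the random range. The medians of the neutrophil and monocyte, endoderm, mitosis, apoptosis and hypoxia lists, none of which stood apart in the main scaling, were negative with library total scaling and with FPKM plus 1. Among named genes, 1810 recomputed values lay within the counting interval, 442 lay outside it and none of those called at 2-fold changed sign. Some of them fell below 2-fold, however. The deposited FPKM of MYC (29.8 and 50.6) and STAT5B (34.7 and 61.2), for instance, were within 2-fold.

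The count of genes at least 2-fold higher was 487 with library total scaling, 346 with FPKM plus 1, 2097 with no filter, 451 with a filter at 100 counts and 340 at the near bound of the interval, against 798. The count of lower genes was 3807 with no filter, 853 with a filter at 100 counts and 786 at the near bound, against 1481. The filters change how many genes are tested (19524 and 8048 against 12939), and the near bound is a stricter threshold by construction. With no filter the stem and progenitor median was -0.79 and stood apart (percentile 0.21), and the epithelial median was -0.037, reversed (percentile 48.8). With a filter at 100 counts the JAK-STAT median was -0.36 (percentile 2.63) and the histone median -0.067 (percentile 45.3), both inside the random range. List means were -0.20 for JAK-STAT and -0.58 for histones, inside the random range, and -0.72 for pluripotency, outside it (percentile 2.13). The length correction gave a respiratory chain median of 0.10 (0.12 with GC content), inside the range, and an apoptosis median of -0.27 (-0.27 with GC content, percentile 1.31), outside it. The length and GC content correction gave a neutrophil and monocyte median of -0.15 (percentile 2.25). The cause was not tested for these lists. Depth limits single genes near the filter: CLDN7, with 11 counts against 20, had an interval of -0.01 to 2.33, so that no difference was detectable at this depth.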

Other observations

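The tests below were chosen after the results were seen, except the GC content test of the ribosomal protein genes, whose prediction was written before its result.

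Apart from LTF and LCN2, the genes of this paragraph were picked after their values were seen, and most lie outside the fixed lists. CAVIN2, GNG11 and NRGN, genes abundant in platelets, were 13.1-fold, 13.1-fold and 11.4-fold lower in the MEIS1-/- library, and PTGIR, the prostacyclin receptor, was 17.0-fold lower. EGF had 785 counts against 50. PKLR, the red cell pyruvate kinase, SLC25A39 and PRDX2 were 7.78-fold, 6.81-fold and 5.24-fold higher. DEFA1B and DEFA3, near-identical neutrophil defensin genes, were together 5.11-fold higher with 2683 counts against 11444, and LTF, another neutrophil granule gene, had 22 counts against 224. LCN2 of the epithelial list, also a neutrophil granule gene, went the other way with 84 counts against 17. The monocyte and macrophage genes CD14, CD163 and CSF1R were 3.31-fold, 3.08-fold and 2.33-fold lower, unlike LYZ of the same fixed list at a log2 ratio of 0.61. ACTB lay at a log2 ratio of 0.03 and GAPDH at 0.30, and ACTB turns negative under library total scaling and with FPKM.

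NUDT4P2 had 756 counts against 0, while its near-identical copies NUDT4 and NUDT4B had 2094 against 4465 and 363 against 1964. Summed over the 3 genes the family was 2.40-fold higher. Of 4008 genes with several transcripts and at least 100 counts in both libraries, 3 differed by 1.5-fold or more in mean transcript length, all shorter in the MEIS1-/- library.

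The first pattern weighed was the lower megakaryocyte and platelet genes. Displacement by globin reads would lower all other genes alike by at most -0.20 on the log2 scale, and with globins left out of the totals the surface receptor median was -2.80, which argues against it as the cause. A length trend is also argued against, since the median after the length correction was -2.74. Fewer megakaryocytes in the MEIS1-/- culture, or megakaryocytes with lower expression of these genes, may each account for it as hypotheses. The counting intervals of 20 of 24 receptor genes excluded the list's median, and those of ITGB3 (-3.16 to -2.98) and ITGA2B (-2.45 to -2.33) did not overlap. Within counting error the receptor genes were therefore not all lower by 1 common factor. The same held for 25 of 30 cytoskeleton genes and 29 of 34 erythroid genes around their own medians. The intervals leave out other differences between the libraries, and how far other cells of the culture express these genes is not known. This spread therefore does not decide between the hypotheses. Each library may hold RNA of every cell type of the culture, so fewer megakaryocytes and lower expression within them cannot be told apart. With 1 culture per genotype, a difference between cultures cannot be told from one between genotypes either.

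The second pattern was the lower interferon-response genes, which may follow a smaller share of a cell type that expresses them or a lower response within cells. Of the 21 lower genes, 1 (IFI27) had an interval wholly below those of the platelet glycoprotein genes GP1BA, GP1BB, GP5, GP6 and GP9. The interval of P2RY12 in the surface receptor list (-12.09 to -4.27, 131 counts against 1) overlapped that of IFI27. The monocyte and macrophage genes compared were CD14, CSF1R, CD163, CD68, FCGR3A, VCAN and IRF8. Of the 21 genes, 7 (IFIT1, MX1, OAS1, OAS2, OAS3, IFI6 and IFI27) had an interval wholly below those of all of them. These monocyte and macrophage genes were picked after they were seen to be lower. Others of the same fixed list were not, with LYZ, ITGAX and MNDA at 0.61, 0.44 and 0.38, and TYROBP, FCN1 and AIF1 at 0.20, 0.13 and 0.01 (these 3 negative under library total scaling and with FPKM). FCGR1A of that list lay at -0.76, and MARCO, below the filter, had 18 counts against 3. That list holds neutrophil genes as well, so its members that were not lower need not come from monocytes and macrophages alone. The counts therefore decide nothing about a loss of either cell type, and exposure to interferon was not tested.

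The third pattern was the higher ribosomal protein genes. GC content is argued against, since the median after its correction was 0.65 against 0.67 before. A trend with abundance is argued against as the whole cause by 171 other genes of like abundance, whose median was 0.23 against 0.67. It may still account for part of the pattern, and a joint correction for abundance and length was not run. Transcript length may also account for part of the pattern, since the length correction lowered the median to 0.29 (percentile 98.2, still above the random range). That correction cannot tell a technical length bias from short transcripts that differ between cell types, so the rest and its cause stay open.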
